A study of Mus musculus with 2 samples.

How the data were processed

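Trimethylation of lysine 36 of histone H3 (H3K36me3) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse lung at embryonic day 15.5. Per the labels, the tissue came from B6NCrl embryos of both sexes and was pooled, from 78 embryos for replicate 1 and from 62 embryos for replicate 2. The replicates are biological. Replicate 1 joined 3 technical replicates and replicate 2 joined 2. Both form a single group, so no comparison between groups was possible.

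The authors deposited 4 peak lists on the mouse build mm10. There is 1 list for each replicate, 1 for both replicates pooled, and a replicated list that, per the deposited README, was derived from the other 3 lists. Per the same README, the lists rest on filtered alignments and a control alignment. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a signal value, which is the authors' own enrichment value with a definition that the deposited files do not state. The authors also gave each peak a −log10 p and a −log10 q, and a display score that was deposited with the lists and not used here. Signal values, p and q were used to describe, rank and filter peaks within a list. Ratios of these values between the replicates were computed only at peaks or genes with a value in both. Every peak in all 4 lists had a −log10 p of at least 2, which corresponds to p of 0.01 or lower. The lists hold no read counts, so the depth of each library is unknown. No interval that needs the depth is given, and a gene without a peak may still carry signal below the peak threshold. The control alignment was not analysed here.

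Gene bodies were the spans from start to end of genes in GENCODE vM21, which is on the same build, and every peak end fell within its chromosome. Genes were protein-coding, at least 1000 bp long and on the 21 primary chromosomes, which left 21221 of 21938. For each gene and replicate, the percent of the gene body under peaks was computed, and a gene was called marked when at least 10% was covered in each replicate. Values are given as mean ± SD over n = 2. For the median of a gene list, the value is the median over its members of their mean coverage. Its SD is that of the medians of the 2 replicates. Profiles used marked genes of at least 5000 bp. Exons were the union of a gene's annotated exons, and introns the remaining bases. A peak counted as shared when a single peak of the other replicate covered at least 50% of it. Several peaks that reached 50% only together did not count. Chance was taken from 100 shuffles of the other list within each chromosome, and again with the shuffled peaks kept inside genes. Joined stretches outside genes allowed gaps of up to 3000 bp. Percent coverage says where peaks lie and depends on the peak threshold, so it is not an amount of the mark.

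The 24 gene lists were fixed before the data were examined. Each was tested by the median percent covered of its members against 10000 random lists of the same size, matched on 10 classes of gene length, with a two-sided permutation p and Benjamini-Hochberg adjustment over the 24 lists. The smallest p these permutations can give is 0.0002 before adjustment. Genes are not independent replicates, so such a p describes how far a list stood apart from other genes in these libraries. The test was checked on simulated lists of 25 genes, with fewer random lists than 10000. At an unadjusted p under 0.05, which is less strict than the adjusted p used for the lists, it called 3 of 100 lists with no shift. It called 46 of 100 raised by 10 percentage points and 100 of 100 raised by 20. The check used the median and simulated no lowered list, so it does not cover the comparison by the mean given later.

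The genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 genes of at least 5000 bp with the highest coverage, the 2 highest and the lowest member of each list, the 5 genes of at least 5000 bp with the largest difference between replicates each way, the 5 replicated peaks of highest signal value, the 5 longest stretches outside genes, and Setd2, Nsd1, Nkx2-1, Sftpc, Col1a2, Pecam1 and Alb. The rule for peaks was written for a fold. The signal value was used in its place, since the files do not say that it is a fold.

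Alternatives were a q of 0.01 or lower, a signal value of at least 3, joined peaks, other coverage minimums, other overlap minimums, other gene sets, each replicate alone and the replicated list. A mean in place of the median, exons and introns of the last 33.3% of gene bodies, and genes over 2 kb from other genes were added after seeing the data. A gene was at first taken as intronless when its merged exons formed a single block. That definition fused exons over retained introns in 82 of 564 genes, and it was replaced, after its result had been seen, by the absence of any annotated transcript with more than 1 exon. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.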

Results

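H3K36me3, a histone mark laid down along transcribed genes, was mapped in lung tissue of mouse embryos at day 15.5, when the epithelium is branching within its mesenchyme. A single group of 2 biological replicates was collected. Replicate 1 gave 178261 peaks on the primary chromosomes, which covered 104.8 Mb, and replicate 2 gave 134094 peaks, which covered 55.7 Mb. Their median widths were 364 bp and 303 bp. Of the peaks of replicate 1, 87.7% had a q of 0.01 or lower, against 59.4% in replicate 2. The read depth behind these lists is unknown. The pooled list held 171028 peaks over 112.1 Mb, and the replicated list held 100004 peaks over 92.5 Mb, with a median width of 613 bp and a widest peak of 21267 bp.

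The 1st question was where in the genome the mark lay. Protein-coding gene bodies held 94.97% ± 0.31 (SD, n = 2) of peak bases, although they make up 38.2% of the genome, a 2.49-fold excess. Shuffled peaks placed 42.0% of their bases there, with a highest value of 42.4% in replicate 1 and 42.5% in replicate 2. In all, 5914 of 21221 genes (27.9%) were marked in both replicates, and 713 had at least 50% of their body covered in both. A further 2067 genes were marked in replicate 1 only and 21 in replicate 2 only. No peak of either replicate lay in 9865 genes (46.5%).

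The 10 most covered genes of at least 5000 bp ranged from Zfp110 to Kmt2b. Zfp110 (ENSMUSG00000058638.14, chromosome 7, 12834761 to 12850577), a zinc finger gene, was covered over 86.7% ± 4.00 (SD, n = 2) of its body. Kpnb1 (chromosome 11, 97159714 to 97187881), the nuclear import receptor importin beta, was covered over 86.4% ± 5.41. Mybbp1a (86.0% ± 4.90), the condensin subunit gene Ncapd2 (85.6% ± 5.54), Gigyf1 (84.7% ± 11.96) and the zinc finger gene Zfp606 (84.7% ± 2.44) followed. Next came Rbm5, an RNA-binding splicing regulator (84.5% ± 5.19), Exosc10, a catalytic subunit of the RNA exosome (83.9% ± 8.83), Sf3b3, a part of the U2 snRNP (83.6% ± 8.998), and Kmt2b, an H3K4 methyltransferase (83.4% ± 6.87). Replicate 1 was the more covered in each of the 10. The differences among them were of the order of their SDs. Mybbp1a, Gigyf1 and Sf3b3 overlap another protein-coding gene, and peaks in the overlapping bases count for both genes.

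**Figure D1:**
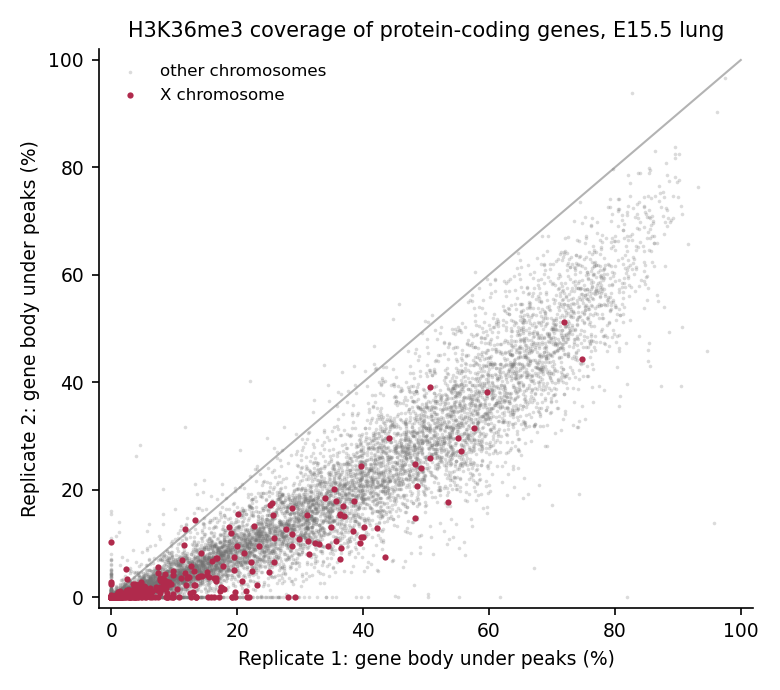
Percent of each protein-coding gene body under H3K36me3 peaks in replicate 1 (x axis) and replicate 2 (y axis), 1 point per gene (21221 genes), with X-linked genes in red and the line of equal values in grey. Most genes with peaks lie below the line, and among the 5914 marked genes 5848 were more covered in replicate 1.

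Coverage within genes was asked next. In 5405 marked genes of at least 5000 bp, the last 33.3% of the gene body was covered over 65.6% in replicate 1 and 42.4% in replicate 2, and the first 33.3% over 24.2% and 13.3%. The 3′ to 5′ ratio was 2.95 ± 0.34 (SD, n = 2). Coverage was 1.30% and 0.669% in the last 1 kb before the gene start, peaked at 68.1% and 44.4% late in the body, and was 48.5% and 28.6% in the 1st kb after the gene end. Exon bases, pooled over all marked genes, were covered over 60.2% and 39.7%, and pooled intron bases over 41.0% and 23.3%. The exon to intron ratio was 1.59 ± 0.17 (SD, n = 2). Within the last 33.3% of gene bodies alone, an alternative chosen after seeing the data, the pooled ratio was 1.254. No ratio was taken within each gene. Pooling therefore cannot separate an exon preference within genes from differences between genes in coverage and intron length.

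**Figure D2:**
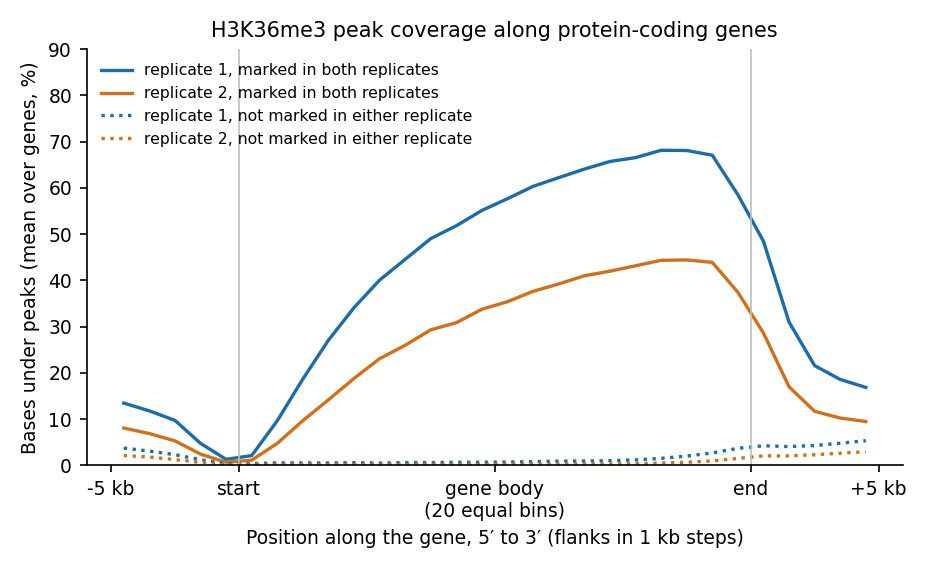
Mean percent of bases under peaks (y axis) in 20 equal bins from gene start to gene end and in 1 kb steps over the 5 kb on either side (x axis), for each replicate. Solid lines are 5405 genes marked in both replicates and dotted lines 10549 genes marked in neither; coverage of marked genes rises along the body to 68.1% in replicate 1 and 44.4% in replicate 2.

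Among the 24 gene lists, cell cycle genes and transcription and splicing genes were the most covered. All 32 cell cycle genes were marked. Their median coverage was 63.2% ± 14.0 (SD, n = 2), against 1.34% in matched random lists. Top2a, which untangles DNA in mitosis, was covered over 81.1% ± 9.48 and Cdk1, the mitotic kinase, over 74.9% ± 13.5. Aurkb had the lowest value of the list, 31.3% ± 11.7. All 31 transcription and splicing genes were marked as well, with a median of 59.7% ± 12.2 against 2.68%. The spliceosome scaffold Prpf8 reached 81.3% ± 8.44 and the RNA helicase Ddx17 80.03% ± 10.4, while Cdc73 of the PAF complex stood at 16.7% ± 9.42. Ddx17 and Cdc73 overlap other protein-coding genes.

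Ribosomal protein genes were marked in 63 of 79 cases, with a median of 44.1% ± 10.3 (SD, n = 2) against 0 in matched lists. Rps3 (73.4% ± 10.1) and Rps15a (72.2% ± 15.8) were the highest, and the X-linked Rpl10 had no peak. Housekeeping genes were marked in 26 of 33 cases, with a median of 41.9% ± 15.3 against 0.272%. They were led by the chaperone Hsp90ab1 (79.7% ± 0.064) and the elongation factor Eef2 (75.4% ± 8.44), and Tuba1b had no peak. Aldoa counts as 2 of the 33, since 2 gene entries carry its symbol. Of the genes that write, erase or read H3K36 methylation, 20 of 29 were marked, with a median of 34.4% ± 14.5 against 2.23%. The demethylase Kdm4a was covered over 79.3% ± 11.9 and the elongation factor Supt6, which is also in the transcription list, over 68.4% ± 11.5. Setd2, the main H3K36 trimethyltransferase, was covered over 45.7% ± 14.7 and Nsd1, which places lower methylation states, over 59.8% ± 17.4. Riox1 had no peak.

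Zfp genes, the numbered zinc finger genes, were marked in 205 of 365 cases. Their median was 19.6% ± 8.51 (SD, n = 2) against 1.95%. Zfp869 was covered over 97.1% ± 0.52 and Zfp174 had no peak. These 6 lists stood above matched genes by the permutation test, each with an adjusted p of 0.0008, from the smallest p the permutations can give, and each also in either replicate alone.

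In the lung mesenchyme list, 11 of 32 genes were marked. Fn1, which encodes fibronectin, was covered over 67.0% ± 18.5 (SD, n = 2), Col1a1 over 51.6% ± 18.0 and Col1a2 over 43.2% ± 19.1, the last 2 for the chains of type I collagen. Foxf1, a mesenchymal transcription factor, had no peak. The list's median was 11.3% ± 6.90 against 1.05% in matched lists, which did not pass the permutation test after adjustment (adjusted p = 0.0501).

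In the lung epithelium list, 4 of 32 genes were marked. They were Lpcat1, an enzyme of surfactant lipid synthesis (39.2% ± 17.3, SD, n = 2), Etv5 (23.2% ± 16.01), Abca3, the surfactant lipid transporter (19.5% ± 10.1), and Ager (16.7% ± 5.08). Abca3 and Ager were named after their values were seen. Ager is 3.08 kb long and lies within 0.461 kb of Pbx2, which was covered over 23.9%. No peak of either replicate lay in 18 of the 32 genes, among them Nkx2-1, the lung lineage transcription factor, Sftpc, for surfactant protein C, and Aqp5. Nkx2-1 (4.95 kb), Sftpc (3.13 kb) and Aqp5 (4.05 kb) are short as well. They may still carry signal below the peak threshold, and the lists do not separate the cell types of the lung.

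Of the endothelial genes, 1 of 24 was marked. This was Eng (26.4% ± 18.1, SD, n = 2), which overlaps Fpgs, a gene covered over 23.6%. Egfl7 followed at 8.98% ± 6.79, Pecam1 stood at 0.841% ± 1.19 and Cldn5 had no peak. None of 11 mesothelial genes was marked, with Podxl the highest at 2.68% ± 2.08 and no peak in Aldh1a2. Of the erythroid genes, 1 of 16 was marked, the transferrin receptor gene Tfrc (44.1% ± 14.7). Alas2 followed at 5.59% ± 3.88 and Gata1 had no peak. Of the leukocyte genes, 2 of 18 were marked, Cd68 (83.9% ± 8.01) and Cx3cr1 (13.8% ± 3.405), and Adgre1 had no peak. Both have highly covered neighbours. Cd68 is 1.94 kb long and lies 0.782 kb from Eif4a1, which was covered over 61.9%, and Cx3cr1 overlaps Wdr48, which was covered over 54.2%.

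Markers of tissues other than lung carried almost no peaks. Of the lists above, 10 of 11 mesothelial, 12 of 16 erythroid and 15 of 18 leukocyte genes also had no peak. Only 7 of 24 endothelial and 4 of 32 mesenchymal genes had none. A lack of peaks alone therefore does not set markers of other tissues apart. No gene was marked among 18 of heart muscle, 17 of skeletal muscle, 28 of neurons and glia, 21 of hepatocytes and 22 of kidney and gut epithelium. Their highest members were Ttn at 0.570% ± 0.44 and Scn5a at 0.133% ± 0.19 (heart), Cacna1s at 0.142% ± 0.20 (skeletal muscle), Elavl3 at 0.167% ± 0.24 (neurons), Hnf1a at 1.68% ± 2.38 (hepatocytes) and Vil1 at 1.29% ± 1.83 (gut), all SD with n = 2. Actc1, Acta1, Dlx1, Afp, Alb and Alpi had no peak. The 18 posterior Hox genes, Hoxa10 and Hoxa11 among them, and the 22 germline genes, such as Acrv1 and Bmp15, had none at all. Neither did the 273 vomeronasal receptors, Vmn1r1 and Vmn1r10 among them. Among 1029 olfactory receptors, Olfr543 (2.97% ± 4.20) was the only gene with a peak, in replicate 1; Olfr1 had none. None of 20 histone genes of at least 1000 bp was marked, and any shorter ones were left out. Hist1h2bc stood at 1.07% ± 1.51, Hist1h2be at 0.286% ± 0.40 and H1f0, a replication-independent member of that list, at 0. None of the 10 anterior Hox genes of the lung list was marked either, with Hoxa5 at 3.63% ± 5.14, Hoxa3 at 0.787% ± 0.17 and Hoxa1 without a peak. Of the imprinted genes, 5 of 21 were marked: Nnat (53.2% ± 23.6), Igf2r (47.2% ± 20.4), Impact, Grb10 and Peg3, the last 3 named after their values were seen. Nnat overlaps Blcap, which was covered over 23.1%, and Magel2 had no peak.

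No list lay below matched genes by the median, because the medians of matched random lists were themselves at or near 0. With the mean in place of the median, an alternative chosen after seeing the data, 14 lists lay below. By the same permutation test these were lung epithelium (mean 4.998% ± 3.05 against 11.5%, adjusted p = 0.0331), endothelium (2.42% ± 1.89 against 11.3%, adjusted p = 0.0030), mesothelium (0.0022), erythroid (0.0384), posterior Hox (0.0072) and histone genes (0.0051), and heart, skeletal muscle, neurons and glia, hepatocyte, kidney and gut, germline, olfactory and vomeronasal genes, each with an adjusted p of 0.000343. Leukocyte genes (adjusted p = 0.124), lung Hox genes (0.0635), imprinted genes (0.684) and lung mesenchyme (17.5% ± 8.01 against 11.2%, adjusted p = 0.0533) did not pass this permutation test.

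**Figure D3:**
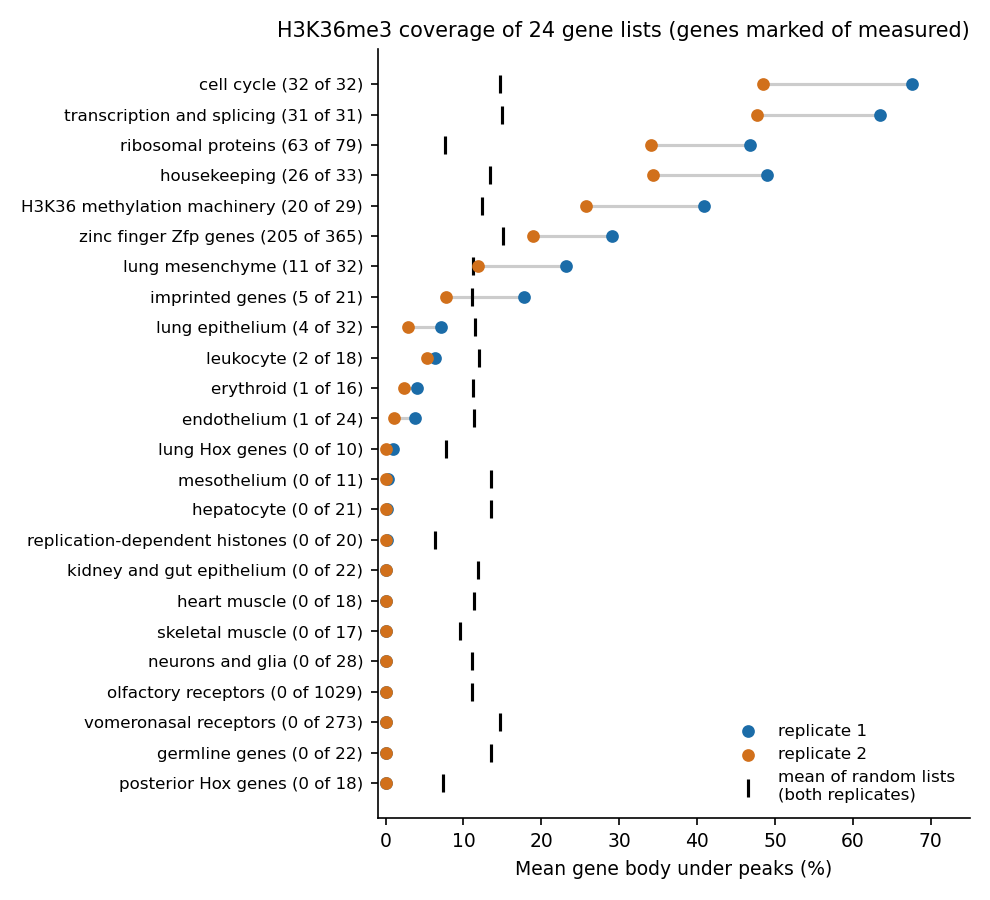
Mean percent of the gene body under peaks (x axis) for each of 24 gene lists (y axis, with marked and measured genes), with 1 dot for each replicate and a black tick for the mean of matched random lists averaged over both replicates. Cell cycle genes were at 67.6% in replicate 1 and 48.5% in replicate 2, while 12 of the 24 lists had no marked gene.

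Chromosomes were compared because the tissue came from embryos of both sexes. On the 19 autosomes, 7.75% ± 3.30 (SD, n = 2) of protein-coding gene-body bases lay under peaks, from 5.52% on chromosome 6 to 11.1% on chromosome 11. On the X chromosome, 1.42% ± 0.97 did. The X to autosome ratio was 0.208 in replicate 1 and 0.135 in replicate 2, so that X lay below each autosome in both replicates. On X, 48 of 877 genes (5.47%) were marked, against 29.1% on the autosomes. None of 163 genes on the Y chromosome was marked.

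**Figure D4:**
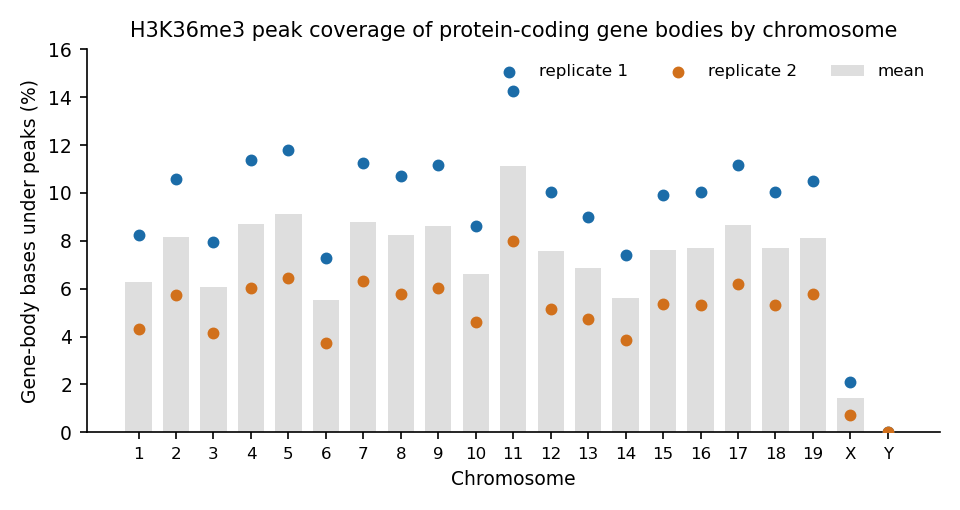
Percent of protein-coding gene-body bases under peaks (y axis) by chromosome (x axis), with a dot for each replicate and a grey bar for their mean. X stands at 2.10% in replicate 1 and 0.733% in replicate 2, below the lowest autosome in each.

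By the authors' signal value, the 5 strongest replicated peaks were from 3101 to 14819 bp wide. Their summits fell in the coding sequence of Zfp146 (chromosome 7, 30160638 to 30164365, signal value 11.7), Plec, for the cytoskeletal linker plectin (chromosome 15, 76169959 to 76184777, 11.2), Zfp865 (chromosome 7, 5027487 to 5034199, 11.1), Zfp777 (chromosome 6, 48022526 to 48029553, 10.8) and Zfp810 (chromosome 9, 22278047 to 22281147, 10.5). The peak at Zfp865 also reaches Ccdc106 and Gm44973. Peaks of replicate 1 covered at least 98.6% of each of the 5 and peaks of replicate 2 at least 82.0%. Of the 100 strongest replicated peaks, 45 lay in Zfp genes, against 1.92% of all replicated peaks.

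Few peaks lay away from genes. Of the replicated peaks, 183 (0.183%) were over 5 kb from any annotated gene, although 44.7% of the genome lies there. The count fell to 47 with a signal value of at least 3 and to 17 over 20 kb from genes. The 183 peaks formed 117 stretches. The 5 longest ran from 7.20 kb to 5.46 kb. The stretch on chromosome Y, 90738658 to 90745852, lay 7.20 kb from its nearest gene, the pseudogene Mid1-ps1. That on chromosome 11, 80410868 to 80417535, lay 5.13 kb from Zfp207. The stretch on chromosome 5, 104581015 to 104587531, lay 26.8 kb from the noncoding gene D930016D06Rik. That on chromosome 2, 84587529 to 84593749, lay 6.32 kb from Ctnnd1, and that on chromosome 4, 12102104 to 12107561, lay 5.86 kb from Rbm12b2. Mean coverage of these stretches by the replicates' own peaks was from 30.8% ± 25.1 (SD, n = 2) near Zfp207 to 53.4% ± 13.1 near Mid1-ps1.

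The last question was how far the replicates gave the same regions. Of replicate 2 peaks, 78.6% were at least 50% covered by a single peak of replicate 1 (95% Wilson interval 78.3% to 78.8%). Shuffled peaks gave 4.15%, and peaks shuffled within genes 8.49%. Of replicate 1 peaks, 25.1% were so covered by a single peak of replicate 2 (24.9% to 25.3%), against 1.93% and 4.01%. These intervals cover counting error only, and the shares depend on the overlap asked for: with at least 1 base they were 87.2% and 49.7%, and with at least 80% of the peak 64.7% and 10.1%. In bases, 83.5% of replicate 2 and 44.4% of replicate 1 were shared, with a Jaccard index of 0.409. Sharing grew with signal value, from 67.3% in the lowest 20% of replicate 2 peaks to 93.6% in the highest 20%, and from 13.8% to 41.6% for replicate 1. Across genes, coverage in the replicates had a Pearson r of 0.954 and a Spearman rho of 0.949 over all 21221 genes, and of 0.916 and 0.921 over the 8002 genes marked in either. Genes are not independent replicates, so no p is given.

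Among genes of at least 5000 bp, the largest differences between replicates were toward replicate 1. Tbc1d13 was covered over 68.0% in replicate 1 and 20.8% in replicate 2, Trmo over 65.4% and 18.4%, Ptrh2 over 55.2% and 9.13%, Pla2g4b over 59.7% and 15.7%, and Dph7 over 57.3% and 13.3%. The largest differences the other way among genes of that length were smaller. Rab26 stood at 8.22% and 15.5%, Kptn at 3.398% and 8.86%, Fcgrt at 0 and 5.08%, Zbtb18 at 14.6% and 19.6%, and Agtrap at 2.52% and 6.95%. Shorter genes differed more, such as Tssk2 (82.0% and 0) and Txndc17 (4.62% and 28.3%), which were named after their values were seen. With a single group of 2, no test of these differences is possible.

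Each replicated peak was also a peak of the pooled list. Of the replicated peaks, 76711 (76.7%) overlapped a peak of each replicate by at least 50% of either peak. In the pooled list the number of such peaks was the same, 76711, which was 44.9% of its peaks. The deposited files do not state by which rule the remaining replicated peaks were kept.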

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

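Of the explanations weighed here, the 2 for the difference between replicates were tested only after that difference had been seen, and for the X chromosome the comparison without members lacking a peak and that of signal values at like coverage were added after the results they bear on. Peaks on unplaced or unlocalized sequence, which no comparison above used, numbered 12 in replicate 1 and 18 in replicate 2. They were picked out as a signal outside the main measurement, and no control library was analysed here to set them against. The highest signal values among them, 8.81 in replicate 1 and 6.30 in replicate 2, lay on the same unlocalized sequence of chromosome 4.

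X-linked gene bodies carried far fewer peaks than autosomal ones. A shortage of broadly expressed genes on X as the whole cause is argued against. Within 10 mostly broadly expressed gene families, the mean coverage of 28 X-linked members was 12.7% against 35.98% for 700 autosomal members. The ratio was 0.352 (95% bootstrap interval 0.209 to 0.507), with 0.425 in replicate 1 and 0.243 in replicate 2. Families were defined by gene names that also take in testis-restricted paralogs such as Usp26 and Taf7l. The 8 X-linked members without a peak were therefore also left out with no autosomal member removed, which gave 0.493 (0.329 to 0.676). The bootstrap intervals given for X resample genes, which are not independent, and hold no variation between the replicates. Gene length and GC content are argued against as well, since X-linked genes had 0.274 of the mean coverage of autosomal genes matched on both (0.238 to 0.326 over 1000 draws). Lower enrichment at X-linked genes, which 1 active X in each cell of tissue from both sexes would give, stays open. Among family members with a peak in both replicates, the median strongest signal value was 3.66 for 16 X-linked and 4.63 for 625 autosomal genes. The ratio of 0.791 (0.668 to 0.859) met the bound set beforehand, a ratio of 0.85 or lower with an interval below 1. The strongest signal value rose with coverage across the autosomal members, however (Spearman rho 0.640, across genes). Against the 20 autosomal members nearest in coverage the median ratio was 0.885 (0.851 to 0.959), and no bound was set beforehand for it. Lower enrichment would itself lower coverage, so matching on coverage can shrink the difference and cannot decide the question. Lower mappability of X, unequal control coverage and lower transcription of these genes were not tested and stay open too.

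Zfp genes were covered more than other genes of their length. Reads shared between paralogs would fall mainly on the repeated zinc finger exons, yet the introns of 357 Zfp genes were covered over 18.4% against 13.9% in length-matched genes (permutation p = 0.0002, the smallest it can give). The excess was larger in exons, 38.1% against 20.2%, so shared reads may still add to it there. A peak can also run from an exon into an intron, so intron coverage cannot exclude a part of shared reads. GC content is argued against, since Zfp genes were at 23.9% against 15.0% in genes matched on length and GC (permutation p = 0.0002). Many Zfp genes lie in clusters and are not independent, and a biological explanation was not tested because the series has no second group.

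Replicate 2 had fewer and shorter peaks than replicate 1. At 74424 pairs of peaks found in both, the median ratio of −log10 p, replicate 2 over replicate 1, was 0.658, and that of signal values was 0.901. These pairs leave out peaks too weak to be found in replicate 2, which can raise both ratios; in the strongest 10% of pooled peaks, of which 6 were missing from replicate 1 and 287 from replicate 2, the ratio of signal values was 0.831. Fewer usable reads and weaker enrichment in replicate 2 cannot be told apart, since either lowers −log10 p and the read numbers are unknown. By bounds written after the difference was seen, a signal ratio under 0.8 was to be read as weaker enrichment. A signal ratio not under 0.8 with a −log10 p ratio under 0.8 was to be read as fewer reads. The pairs met the latter bound, but that reading was not kept, because the choice of pairs can raise the ratios. The numbers of pooled embryos and of technical replicates also differ between the replicates, and their part was not tested.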

How the results depend on the processing

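The mean in place of the median, the last 33.3% of gene bodies and genes over 2 kb from others were chosen after seeing the data; the other alternatives were planned. No result reversed. The 6 lists above matched genes passed under each of the 9 alternatives run for lists; lists below numbered 14 with the mean and 0 under the others, lung mesenchyme passing under none. Without 1 replicate, the share of peak bases in genes ranged from 94.7% to 95.2%, the 3′ to 5′ ratio from 2.83 to 3.20, the exon to intron ratio from 1.70 to 1.75 and marked genes from 5935 to 7981. A signal value of at least 3 gave a share of 95.6%, a 3′ to 5′ ratio of 3.34, an X to autosome ratio of 0.115 and 47 peaks outside genes; over 20 kb from genes 17 remained. Counting only genes that overlap no other gave a share of 72.3%. Such genes cover 30.7% of the genome, against 38.2% for all protein-coding genes, and the excess fell too, from 2.49-fold to 2.35-fold. Genes over 2 kb from others gave a share of 51.6% and a 1.96-fold excess, and all annotated genes gave a share of 95.8%. A coverage minimum of 5% gave an exon to intron ratio of 1.84, and one of 25% gave 1.29 with 3206 marked genes. Genes of at least 20 kb gave a 3′ to 5′ ratio of 2.36, and the last 33.3% of gene bodies an exon to intron ratio of 1.254. Shared peaks moved with each choice, replicate 1 in replicate 2 first: 18.9% and 84.9% at a q of 0.01 or lower, 21.5% and 75.6% at a signal value of at least 3, 49.7% and 87.2% with an overlap of at least 1 base, 10.1% and 64.7% with at least 80%, 28.9% and 73.5% with the longer list shortened by p, and 19.1% and 74.9% with peaks within 1 kb joined. The causes of these moves were not tested. No paired analysis was possible because there is a single group. The unknown depth limits what can be said of genes without peaks.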

Other observations

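Noncoding genes and X-linked exceptions were not part of the comparisons above. Among 4861 noncoding genes over 2 kb from any protein-coding gene, 37 (0.761%) were marked. Mir17hg, the host of a microRNA cluster, was covered over 70.2% ± 15.0 (SD, n = 2), Snhg17, a small nucleolar RNA host gene, over 63.3% ± 6.85, Malat1 over 46.1% ± 11.0 and the imprinted Meg3 over 28.8% ± 15.9. H19 and Neat1 had no peak. These genes were named after their values were seen.

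The most covered of the 877 X-linked genes were Flna, for the actin crosslinker filamin A (61.5% ± 14.6, SD, n = 2), Hcfc1 (59.6% ± 21.5) and Kdm5c (48.9% ± 15.3). Of 4 genes known to escape X inactivation in the mouse, Kdm5c ranked 3, Eif2s3x ranked 5 (44.6% ± 18.4) and Ddx3x ranked 8 (38.2% ± 17.5), while Kdm6a ranked 160 (3.57% ± 2.44). Flna and Hcfc1 were named after their values were seen, and no test was run on 4 genes.

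The hypothesis was tested that intronless protein-coding genes are less covered than intron-containing genes of their length. The prediction was written before its result was seen, but the set of intronless genes was corrected afterwards. Of 482 intronless genes, leaving out chemoreceptors, histones and genes that overlap others, 12 (2.49%) were marked, against 12.8% in matched lists. Their mean coverage was 2.14% in replicate 1 and 0.822% in replicate 2, or 1.48% over both, against 5.65% in matched intron-containing genes (permutation p = 0.0002, the smallest it can give). Before the correction the mean of the set was 2.47%. Lower transcription of intronless genes, which these files do not measure, may account for part or all of the difference.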
